A study of Arabidopsis thaliana with 12 samples.

How the data were processed

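The series holds 12 Affymetrix ATH1 arrays in 4 groups of 3, from roots and leaves of wild type (Col-0) and cys-c1 plants of Arabidopsis thaliana. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, seedlings grew on MS medium with 1% sucrose, with 16 h of light at 20 °C and 8 h of darkness at 18 °C. RNA of 14-day-old plants was extracted with Trizol and cleaned on RNeasy columns, and biotinylated cRNA was made from 4 µg of total RNA. The design text calls the replicates biological, and gives no harvest time or hybridisation batch.

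The deposited values are log2 signals per probe set, made with RMA in the affy package per the submitters' processing notes. RMA corrects background, quantile-normalises arrays and summarises probes. The versions, and whether roots and leaves were normalised together, were not given in the sources used here. The largest gap between sorted values was 0.2 among root arrays, 0.13 among leaf arrays and 0.63 between a root and a leaf array, so tests between tissues compared genotype effects, and levels in roots and leaves are set side by side only as values. Quantile normalisation gives all arrays of a set nearly the same distribution, so that a change in total RNA per cell would not be seen, and the summary narrows differences of dim probe sets. Values carry 2 decimals. For arrays, their number limits the precision.

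Of 22810 probe sets, 64 Affymetrix controls were left out and 22746 were tested without a filter on signal. Genes were named through a table that pairs probe sets with the platform's annotation. It listed 14016 probe sets, of which 13513 had a single gene and 503 had several. The other 8730 were not listed and are unnamed here. Of the single genes, 13436 were matched to RefSeq's gene table (assembly TAIR10.1), and 77 kept the symbol of the probe table. In all 13355 genes were named, 11751 of them by their locus identifier. Named probe sets made up 59.4% of those tested, but 49.0% of those called in roots and 47.1% in leaves. No probe set was named for CYS-C1, so the planned check of the genotype labels by its signal was not run.

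Each tissue was fitted apart with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, as cys-c1 minus wild type over 6 arrays without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Counts of changes of at least 2-fold also needed an absolute log2 change of at least 1. The difference between tissues was the root effect minus the leaf effect in 1 limma fit over 4 group means. Overlap between tissues was set against the overlap of independent lists and tested with Fisher's exact test, one-sided. SD is given over the 3 arrays of a group, and SE is limma's.

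Before the data were examined, 28 gene lists with 551 genes were fixed, as were the tests and the rule for the genes named. The array's named probe sets covered 95 of these genes. The 13 lists with at least 3 named members were tested with camera, which asks whether a list shifted more than other genes, at a preset correlation of 0.01 and with adjustment over the lists. These were root hair growth, expansins and xyloglucan enzymes outside root hairs, alternative respiration and mitochondrial stress, cytochrome c oxidase, hypoxia, antioxidant enzymes, jasmonate, sulfate, auxin, iron, heat shock, touch and wound, and photosynthesis. The 15 others were not tested. Cyanide and cysteine metabolism, phosphate starvation, and xylem markers had no named member and have no value here. The remaining ones covered asparagine and ammonium, root epidermal patterning, ethylene biosynthesis, ethylene signalling, NADPH oxidases, metallothioneins, salicylic acid, aliphatic and indole glucosinolates, the circadian clock, root markers and dividing cells. Within a tissue, the camera calls of these lists that held with a correlation estimated per list were those of the hypoxia and the touch and wound lists in roots. In leaves the estimate was below the preset 0.01 for the hypoxia (-0.036), sulfate (0.0050) and heat shock (-0.30) lists. It was 0.050 for the expansin list and 0.047 for the touch and wound list. All of these leaf calls were lost, so a lost call does not by itself show correlation between members.

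Named genes were the 12 highest and 12 lowest log2 changes per tissue past the threshold, with non-overlapping groups and a single gene. From each list up to 4 members past the threshold were named, or else the 2 with the largest absolute change. For the difference between tissues 5 genes per direction were named, and 10 for probe sets called in both. The 5 measured genes on either side of CYS-C1 on the chromosome were looked up as well.

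The procedure was tested on simulated data with the 22746 probe sets and the real spread. In the root comparison 62.7%, 92.5% and 100% of simulated log2 changes of 0.5, 1 and 2 were recovered, with 4 false among 174 calls. In the leaf comparison the shares were 46.3%, 80.6% and 100%, with 14 false among 165 calls. For the difference between tissues 86% of changes of 1 were recovered, with 10 false among 182 calls. A simulated shift of -0.5 of the root hair list was called in both tissues, with 0 other lists called in the root simulation and 1 in the leaf simulation. The noise was drawn for each probe set independently, so the simulation held no correlation between genes. In the real root data the root hair list had an estimated correlation of 0.34. How camera fares with such correlation was therefore not tested by it.

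Alternatives were a replicate block, renewed quantile normalisation, arrays centred on their medians, only probe sets with a mean of at least 5, an intensity trend with a robust prior, a single fit over all 12 arrays, an adjusted p under 0.01, an unmoderated test, an estimated correlation or fry for the lists, every probe set of a list member, and each array left out in turn. Array weights and all probe sets as the background of camera were added after seeing the data. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.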

Results

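Transcript levels were measured on 12 ATH1 arrays, Affymetrix chips for Arabidopsis thaliana. RNA came from roots or leaves of 14-day-old seedlings of the wild type (Col-0) and of the insertion mutant cys-c1, with 3 biological replicates of each genotype in each tissue per the series' design text. CYS-C1 is the mitochondrial beta-cyanoalanine synthase, an enzyme that joins cyanide, a by-product of ethylene synthesis, to cysteine, and the series title ties it to root hair formation. Array medians lay between 6.88 and 6.92 (log2 signal) in roots and between 6.37 and 6.42 in leaves. The SD of the difference between 2 replicates of a group ran from 0.128 to 0.272 over the probe sets, and a pair shared identical values for 1.67% to 3.47% of them. The lowest mean correlation of an array with its own group, taken across probe sets, was 0.995 in roots (wild type replicate 1) and 0.992 in leaves (wild type replicate 3). The number of arrays limits the precision of every value below. No probe set is paired with CYS-C1 in the probe table used here, so no value is given for it by name and the genotype labels were not checked by it.

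The root comparison asked which transcripts differed between the genotypes in the organ that bears the hairs. Of the 8 named root hair growth genes, 5 fell in cys-c1 roots and none rose. XTH26, a xyloglucan-modifying cell wall enzyme of root hairs, fell by 1.95 on the log2 scale (SE 0.08, n = 3 per genotype), from 7.02 ± 0.12 to 5.07 ± 0.09 (SD). The root hair peroxidase PRX44 (AT4G26010) fell by 1.52 (SE 0.10), the root hair expansins EXPA18 and EXPA7 fell by 0.96 (SE 0.08) and by 0.87 (SE 0.12), and the peroxidase PRX7 (AT1G30870) fell by 0.55 (SE 0.10). In the same roots 4 of 7 named hypoxia response genes rose and all 3 named genes of the rapid touch and wound response fell. The fixed lists held 54 root hair, 19 hypoxia and 17 touch and wound genes, so most members were not measured by name.

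Among the 3 root hair members that were not past the threshold, the receptor kinase FERONIA (FER) had a log2 change of -0.27, SCN1 of -0.17 and RSL3 of 0.01. Adjusted over the list alone, 7 of the 8 members were called. The list as a whole was shifted down, with a median log2 change of -0.71 (camera, adjusted p = 3.39e-11, preset correlation). Its call was lost with an estimated correlation (adjusted p = 0.0760 with that correlation). Green tissue markers, which added shoot material would raise, had a median log2 change of -0.04 in the same root samples.

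The hypoxia genes that rose in roots were HUP9 (AT5G10040, log2 change 2.60, SE 0.11), WIP4 (AT4G10270, 1.61, SE 0.10), HRA1 (AT3G10040, 1.08, SE 0.09) and HUP32 (AT1G33055, 0.76, SE 0.10). HRA1 is a trihelix transcription factor of the hypoxia response, and WIP4 belongs to a wound-responsive family. The fermentation genes LDH (AT4G17260) and PDC2 had log2 changes of 0.26 and 0.17, which were not past the threshold, and HUP26 (AT3G10020) had -0.12. Of the 7, 5 were called when adjusted over the list alone. The list was shifted up in roots (camera, adjusted p = 3.39e-11), and its call held with an estimated correlation (adjusted p = 0.0319).

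The touch and wound genes that fell in roots were the zinc finger repressor ZAT10 (STZ, log2 change -1.68, SE 0.09), the transcription factor WRKY53 (-0.79, SE 0.11) and the calmodulin-like CML38 (-0.60, SE 0.11). All 3 were also called when adjusted over the list alone. The shift of this list was past the threshold with the preset correlation (camera, adjusted p = 1.10e-07) and with an estimated one (adjusted p = 0.0319).

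Alternative respiration and mitochondrial stress genes moved both ways in roots. HRG1 (AT2G41730) fell by 1.90 (SE 0.10), the glutathione transferase GSTU25 by 0.67 (SE 0.08) and the mitochondrial small heat shock protein HSP23.5 (AT5G51440) by 0.59 (SE 0.08), whereas AT12CYS (AT5G09570) rose by 0.64 (SE 0.09). The other 6 of the 10 named members, the NADH dehydrogenases NDB1, NDB2, NDB3, NDB4 and NDC1 and the stress marker UPOX, were not past the threshold. The 4 called genes were the same number when adjusted over the list alone. The list was shifted down (camera, adjusted p = 0.00474), a call lost with an estimated correlation (adjusted p = 0.186).

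Auxin response and transport genes were shifted up in roots (camera, adjusted p = 0.0163, and 0.262 with an estimated correlation). By fry, which tests the list against no change and not against other genes, the adjusted p was 0.0655. LBD29 and LBD16, which act downstream of auxin in lateral root initiation, rose by 0.39 (SE 0.08) and 0.34 (SE 0.08). The other 5 of 7 members were not past the threshold, and 3 were called when adjusted over the list alone. Both named aliphatic glucosinolate genes rose: BCAT4, the aminotransferase that starts methionine chain elongation, by 1.07 (SE 0.07), and UGT74C1 (AT2G31790), a glucosinolate glucosyltransferase, by 0.50 (SE 0.12). A list of 2 members was not tested as a group.

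Of the 5 sulfate assimilation genes, the ATP sulfurylases APS4 and APS3 fell by 0.56 (SE 0.08) and 0.46 (SE 0.08). Adjusted over the list alone, 4 members were called. The list median was 0.08 and its mean -0.11, of opposite sign, and the list was not called (camera, adjusted p = 0.701). The expansin EXPB1 fell by 0.44 (SE 0.11), alone among 9 named expansins and xyloglucan enzymes outside root hairs (list adjusted p = 0.189, 1 called over the list alone). GRX480, a glutaredoxin of the salicylic acid response, fell by 0.31 (SE 0.07), while SAG101 of the same untested list had a log2 change of 0.14.

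No named member passed the threshold in roots for 6 more tested lists. These were cytochrome c oxidase and cytochrome c (10 members, adjusted p = 0.701), antioxidant enzymes (5, adjusted p = 0.751), jasmonate biosynthesis and response (4, adjusted p = 0.678), iron uptake (3, adjusted p = 0.701), heat shock (3, adjusted p = 0.678) and photosynthesis (5, adjusted p = 0.678). The widest log2 changes among their members included COX6B2 (AT5G57815) at 0.18, TAPX at -0.16, PDF1.2b at 0.12, PYE at -0.21, HSP17.6C (AT1G53540) at -0.21 and LHCB4.1 at -0.11. The list median of the cytochrome c oxidase genes was -0.01 and their mean 0.01, of opposite sign. Lists with fewer than 3 named members were not tested. Their members other than BCAT4, UGT74C1 and GRX480 were not past the threshold in roots, with log2 changes of -0.21 for the ethylene-forming oxidase ACO3 (AT1G12010), 0.24 for RTE1 and 0.05 for EIN3. Adjusted over the list alone, ACO3 and RTE1 were called. In the same lists, the patterning gene TRY was at -0.04, the NADPH oxidase RBOHE (AT1G19230) at -0.01, the metallothionein MT1C at -0.13, UGT74B1 at -0.07 and the clock gene GI at 0.05. PYK10, an endodermis-associated glucosidase, was at 0.08, the replication gene MCM7 (PRL) at -0.17, and the asparaginases ASPGA1 and ASPGB1 were at 0.06 and -0.11.

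Outside the lists, 2 peroxidases were among the greatest rises in roots, AT5G19890 with a log2 change of 2.40 (SE 0.10) and AT1G49570 with 2.32 (SE 0.10). The rises that followed were AT4G33560 (1.99), a wound-responsive family member, AT4G33720 (1.92), of the pathogenesis-related protein 1 family, and AT2G17850 (1.86), a rhodanese-domain protein. Next came the lectin AT5G35940 (1.65), AT2G30670 (1.59), AT5G52710 (1.53), AT4G22610 (1.34) and AT3G29970, from 5.64 to 6.93. Apart from the list members, the falls were greatest for ECS1 (-2.06, SE 0.09), the jasmonate-linked factor ORA47 (-1.76, SE 0.18), the AP2/ERF gene AT1G19210 (-1.75) and AT1G15010 (-1.75). They went on with AT4G27657 (-1.69), AT4G27654 (-1.67), the germin-like AT5G38910 (-1.59), AT5G17350 (-1.54) and AT4G25790 (-1.53), another pathogenesis-related protein 1 relative. Of the 10 measured genes nearest CYS-C1 on the chromosome, only AT3G61390 was past the threshold (log2 change -0.87, SE 0.12, adjusted p = 0.00109). Beyond these 10 but close by in locus number, AT3G61260 and AT3G61300 were also called in roots, both in the same direction. The unnamed probe set with the greatest fall in both tissues, singled out after its values were seen, fell by 6.07 (SE 0.09) in roots, from 11.84 ± 0.07 to 5.77 ± 0.17 (SD).

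Over the 22746 probe sets tested in roots, limma called 1238, of which 563 were higher and 675 lower in cys-c1 (45.5% higher). With each array centred on its median the balance turned, to 639 higher and 606 lower (51.3% higher). A change of at least 2-fold was found for 151 of them, 52 higher and 99 lower, and 607 of the 1238 pair with a single gene. At an unadjusted p under 0.05 there were 3438, and the 2 genotypes did not overlap for 19.4% of probe sets, where chance gives 10%. The count fell to 808, 801 and 751 without cys-c1 replicate 1, 2 and 3, and was 1901 without wild type replicate 1, while an unmoderated test called 321 (with 32 of the 53 named root calls) and an adjusted p under 0.01 left 726. The auxin list call was lost without wild type replicate 1 (adjusted p = 0.0726) and without cys-c1 replicate 2 (adjusted p = 0.0772), and that of EXPB1 without any array but wild type replicate 1 (adjusted p up to 0.197) and with centred arrays (0.0569). EXPB1 and GRX480 were not called in a single fit over 12 arrays (adjusted p = 0.192 and 0.0559). Calls were also lost for GRX480, UGT74C1 and LBD16 without wild type replicate 2 or any cys-c1 replicate (up to 0.146, 0.162 and 0.133), and for LBD29 without wild type replicate 3 or cys-c1 replicate 1 or 2 (up to 0.0722).

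**Figure D1:**
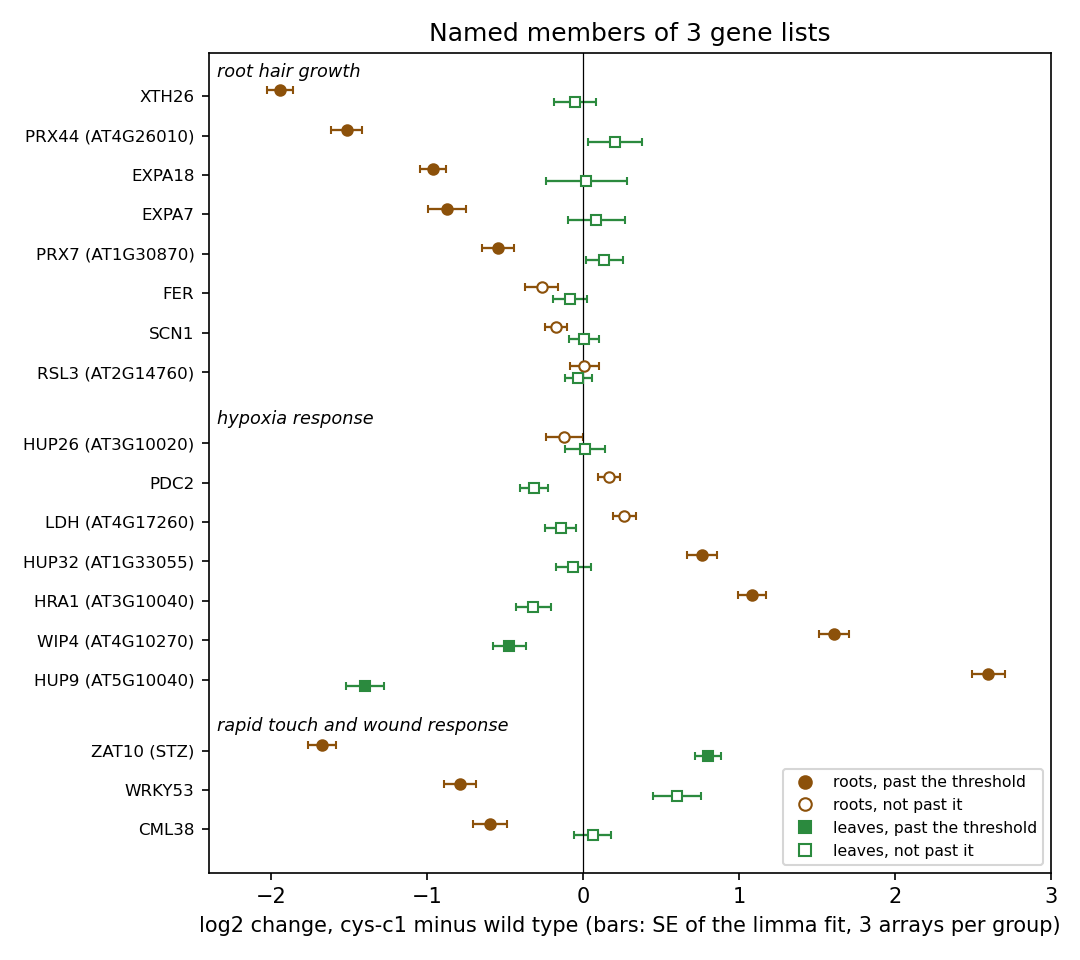
Log2 change in cys-c1 against wild type (horizontal axis) for the named members of the root hair, hypoxia and touch and wound lists, in roots (circles) and leaves (squares), with the SE of the limma fit as bars, 3 arrays per group; filled symbols were past the adjusted p threshold of 0.05. Root values of 5 root hair genes lie between -1.95 and -0.55, and HUP9 and ZAT10 lie on opposite sides of 0 in the 2 tissues.

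The leaf comparison asked the same of green tissue, which carries no root hairs. In leaves AT1G73120 had the greatest named rise, 2.53 on the log2 scale (SE 0.12, n = 3 per genotype), followed by AT1G05575 (1.85, SE 0.10) and AR781 (1.48, SE 0.10). The rhodanese-domain gene AT2G17850 and the hypoxia gene HUP9 (AT5G10040) fell by 1.54 (SE 0.12) and by 1.40 (SE 0.12). No named member of the root hair list was past the threshold in leaves (8 members, median log2 change 0.01, camera adjusted p = 0.771). The 3′ minus 5′ difference of the actin control transcript, a measure of RNA integrity, differed by -0.36 (log2) between cys-c1 leaves, at 3.73 ± 0.11 (SD), and wild type leaves (exact permutation test, 2-sided p = 0.1, the smallest that 3 against 3 allows).

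Of the hypoxia response genes, HUP9 and WIP4 (AT4G10270, log2 change -0.47, SE 0.11) fell in cys-c1 leaves, and the other 5 of 7 members were not past the threshold. Adjusted over the list alone, 4 were called. The list was shifted down (camera, adjusted p = 5.79e-04), a call lost with an estimated correlation (adjusted p = 0.168). The estimate was -0.036, below the preset 0.01, so that loss does not show correlation among the members. Of the 3 touch and wound genes, ZAT10 (STZ) rose by 0.80 (SE 0.08), WRKY53 had a log2 change of 0.60 and CML38 of 0.06. Adjusted over the list alone, 2 of them were called. That list was shifted up (camera, adjusted p = 0.00351; adjusted p = 0.168 with an estimated correlation).

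Expansins and xyloglucan enzymes outside root hairs were shifted up in leaves, where XTH19 rose by 0.62 (SE 0.09), EXPA8 by 0.55 (SE 0.13) and XTH18 by 0.51 (SE 0.10). The other 6 of 9 were not past the threshold, and 4 were called when adjusted over the list alone (camera, adjusted p = 0.0173; adjusted p = 0.185 with an estimated correlation). Sulfate assimilation genes were shifted up by the same test (adjusted p = 0.0173; adjusted p = 0.168 with an estimated correlation and 0.134 with only probe sets of a mean of at least 5), although only APS3 of the 5 rose (0.72, SE 0.12). The members called when adjusted over the list alone were 3. None of the 3 heat shock genes was past the threshold, with log2 changes of -0.53 for HSP22, -0.46 for HSP17.6C and -0.32 for HSP15.7, and 2 were called over the list alone. Their list was called lower (camera, adjusted p = 0.0128; adjusted p = 0.168 with an estimated correlation).

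Single members of other lists were also past the threshold in leaves. The iron deficiency factor BHLH101 rose by 1.04 (SE 0.15) and F6H1 (AT3G13610), which makes iron-mobilising coumarins, fell by 0.53 (SE 0.11), while PYE of the same 3 was at 0.02. Adjusted over that list alone 2 were called, and the list was not (adjusted p = 0.771). The auxin repressor IAA29 fell by 0.67 (SE 0.09), the 1 call among 7 auxin genes on either adjustment (list adjusted p = 0.206). UGT74C1 rose by 0.39 (SE 0.09), with BCAT4 at 0.27. Both glucosinolate genes were called over their list alone. The clock gene GI fell by 0.45 (SE 0.10).

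For the other tested lists no named member passed in leaves: alternative respiration and mitochondrial stress (10 members, adjusted p = 0.771, 1 called over the list alone), cytochrome c oxidase (10, adjusted p = 0.324), antioxidant enzymes (5, adjusted p = 0.206), jasmonate (4, adjusted p = 0.705) and photosynthesis (5, adjusted p = 0.865). Their widest log2 changes were HSP23.5 (AT5G51440) at -0.36, COX5C (AT2G47380) at -0.25, MDAR2 at 0.26, PDF1.2 at -0.46 and SBPASE at -0.08. The remaining genes, whose lists were too short to test, had log2 changes in leaves of 0.06 for ACO3, 0.03 for RTE1, -0.13 for EIN3, -0.10 for TRY, 0.15 for RBOHE, -0.19 for MT1C and 0.15 for UGT74B1. PYK10 was at 0.28, MCM7 at -0.02, GRX480 at -0.07, SAG101 at -0.14, ASPGA1 at -0.04 and ASPGB1 at 0.23.

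Further named rises in leaves were AT1G72920 (1.34) and AT1G66090 (1.16), both of the Toll-interleukin receptor domain family of immune proteins, AT2G39650 (from 6.72 to 8.02), AT4G29700 (1.21) and the RING finger gene AT5G47610 (1.08). They were followed by AT4G37290 (1.03), AT1G35210 (0.95) and the pectin-modifying AT1G05310 (0.94). The falls included the lipid transfer protein gene AT4G12490 (-1.39), AT4G39675 (-1.38), the chitinase relative AT2G43620 (-1.25), the receptor kinases AT3G46280 (-1.24) and AT1G51850 (-1.20), and AT5G66985 (-1.10). AT1G19530 (-1.04), AT2G16660 (-1.01), AT4G19430 (-0.97) and AT5G39520 (-0.96) completed the named falls. Their SE ranged from 0.09 to 0.19. The same unnamed probe set fell by 6.83 (SE 0.14) in leaves, from 12.51 ± 0.08 to 5.67 ± 0.29 (SD).

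In leaves limma called 734 of 22746 probe sets, 512 higher and 222 lower (69.8% higher), of which 346 pair with a single gene. A change of at least 2-fold was found for 51, 31 higher and 20 lower. At an unadjusted p under 0.05 there were 3746, and the genotypes did not overlap for 21.1% of probe sets against the 10% chance gives. The count was 467 and 363 without wild type replicate 1 and 2, and 306, 272 and 296 without cys-c1 replicate 1, 2 and 3, while an unmoderated test called 26 (with 6 of the 40 named leaf calls). It was 1668 in a single fit over 12 arrays and 1143 with an intensity trend and robust prior. Array weights, chosen after seeing the data, gave 1153, and an adjusted p under 0.01 left 243. With the replicate number as a block the count was 441, and the calls of WIP4, XTH18, GI, F6H1, UGT74C1 and AT3G01830 were lost. The expansin and sulfate list calls were lost without wild type replicate 3 (adjusted p = 0.0751 and 0.184) and the expansin call also without cys-c1 replicate 3 (adjusted p = 0.0505). Calls of single genes were lost without any array for EXPA8 and UGT74C1 (adjusted p up to 0.166 and 0.178; UGT74C1 also with renewed quantile normalisation, 0.0556, or centred arrays, 0.0546), any but cys-c1 replicate 3 for WIP4 (0.166), any but wild type replicate 3 for XTH18 and GI (0.107 and 0.145), wild type replicate 1 or 2 or cys-c1 replicate 1 or 2 for F6H1 (0.135), and cys-c1 replicate 2 or 3 for APS3 (0.0586).

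**Figure D2:**
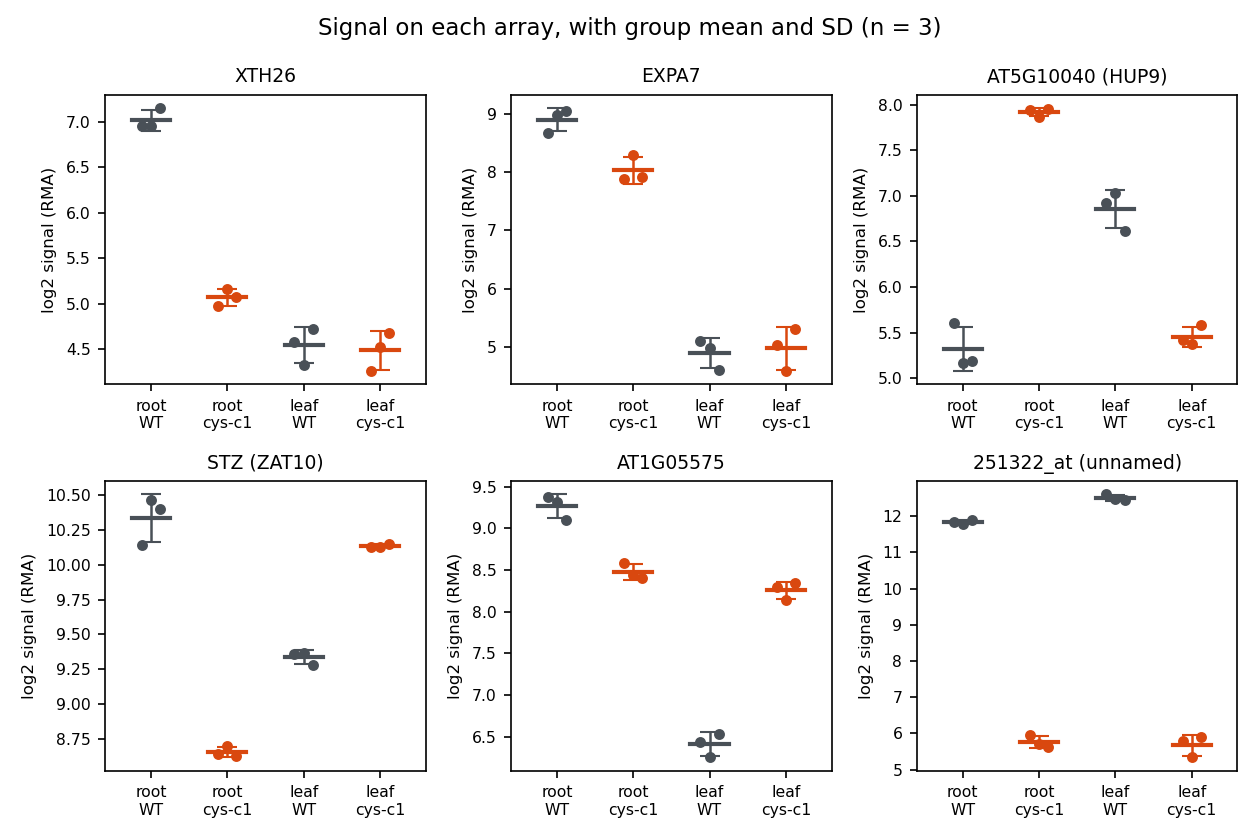
Log2 signal on each array (points) for 5 named genes and the unnamed probe set with the greatest fall, by tissue and genotype, with the group mean and SD (n = 3) as bars. ZAT10 lies near 8.66 in cys-c1 roots against 10.33 in wild type roots and near 10.14 in cys-c1 leaves against 9.34 in wild type leaves.

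The effect of the mutation was then compared between the tissues in a single limma fit over all 12 arrays. It was more positive in roots for HUP9 (AT5G10040), by 4.00 on the log2 scale (SE 0.17, adjusted p = 2.08e-09), and for the rhodanese-domain gene AT2G17850, by 3.40 (SE 0.18). AT4G33560 (2.86, SE 0.23) and the peroxidases AT1G49570 (2.64, SE 0.14) and AT5G19890 (2.46, SE 0.13) followed. On the other side were AT1G05575, with a difference of -2.64 (SE 0.14, adjusted p = 1.37e-08), ZAT10 (STZ, -2.48, SE 0.12), AT4G29780 (-2.31, SE 0.11), AT1G73120 (-2.29, SE 0.15) and AR781 (-2.24, SE 0.13). Among the root hair genes, the effect differed for XTH26 (-1.89, adjusted p = 2.79e-06), PRX44 (-1.72, adjusted p = 1.27e-04), EXPA7 (-0.96, adjusted p = 0.0332) and PRX7 (-0.68, adjusted p = 0.0230). For EXPA18 the difference was -0.98, and it was not past the threshold (adjusted p = 0.0838). Those genes were dim in wild type leaves, between 4.28 for PRX44 and 5.29 for EXPA18, against 7.02 to 10.83 in wild type roots. In all, the effect differed for 1226 of 22746 probe sets, 453 more positive and 773 more negative in roots, and 282 differed by at least 2-fold. Of the 1226, 597 pair with a single gene. Harvest times and batches are not given, so an organ difference cannot be told apart from handling that differed between root and leaf samples.

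Probe sets past the threshold in both tissues held more genes that went opposite ways than the same way. The 10 named genes with the largest smaller change all did so. AT2G17850 (1.86 in roots, -1.54 in leaves), HUP9 (2.60, -1.40), AT5G66985 (1.08, -1.10), AT4G33560 (1.99, -0.87) and AT4G39675 (0.87, -1.38) rose in roots and fell in leaves. AT1G35210 (-0.98 in roots, 0.95 in leaves), AT4G29780 (-1.39, 0.92), AT2G25735 (-0.91, 0.92), the EF-hand gene AT3G01830 (-1.06, 0.82) and ZAT10 (-1.68, 0.80) fell in roots and rose in leaves. In total 197 probe sets were called in both, where independent lists would share 39.9 (Fisher's exact test across probe sets, one-sided p = 1.01e-83; probe sets are not independent replicates). Of these, 92 fell in roots and rose in leaves (15.2 by independence) and 33 did the reverse (5.49), which makes 125 in opposite directions, 63.5%. Another 48 rose in both (12.7) and 24 fell in both (6.59). Across all probe sets the log2 changes in the 2 tissues had a Pearson r of 0.010 and a Spearman rho of 0.014. The tissues share no array, and the limit of unknown harvest times and batches holds here too. Without cys-c1 replicate 1, 2 or 3 or wild type replicate 2 of leaves, the overlap was 107, 100, 113 or 129, it was 301 with array weights, and the leaf call of AT4G33560 was lost without cys-c1 replicate 2 (adjusted p = 0.0514) and that of AT3G01830 without any leaf array but cys-c1 replicate 1 (up to 0.141).

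**Figure D3:**
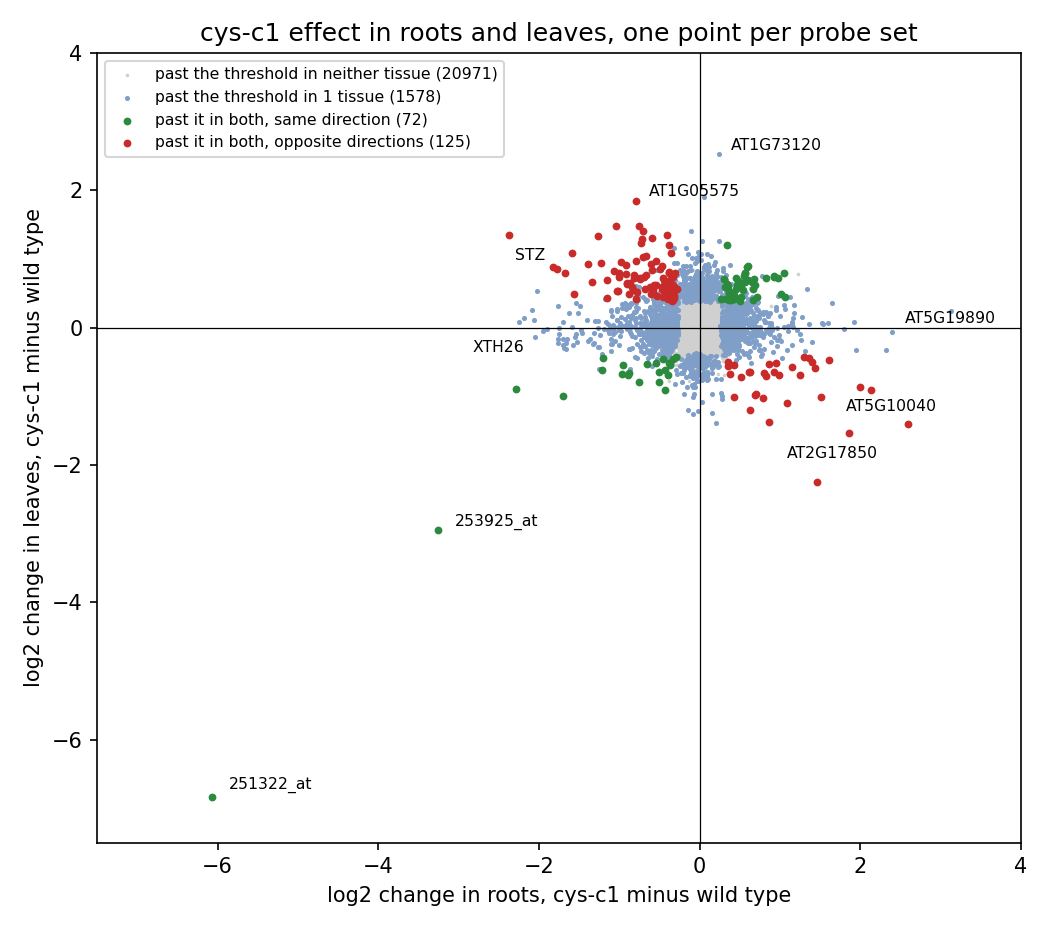
Log2 change in cys-c1 against wild type in roots (horizontal axis) and leaves (vertical axis), one point per probe set, coloured by whether it was past the adjusted p threshold of 0.05 in neither tissue, in 1 tissue, or in both. The 125 probe sets past it in opposite directions lie in the upper left and lower right, and an unnamed probe set lies apart at -6.07 and -6.83.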

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

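The split counts were planned, and leaving out arrays for the hypoxia and touch lists was set before its values were seen, while the tests of list differences between tissues on which it rests and those of array shifts and scaling, handling, shoot tissue, single arrays for the root hair list, root hair cell number, wild type replicate 3 of leaves and RNA quality were chosen only after the results were seen. The effect of cys-c1 differed between roots and leaves, by the test of the difference in a limma fit over 12 arrays, for 1226 probe sets. This real value was not reached by any other of 100 drawn splits, whose highest count was 345. Chance was so excluded at 0.05 only for the case of no genotype effect in either tissue. The splits relabel arrays within a tissue and do not test whether effects present in both tissues are equal. For the 197 probe sets called in both tissues no other of the 100 splits could share a call, since every other split of a tissue's arrays called 0 probe sets, so the count of 1 split as large says nothing of chance there.

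Of the 112 probe sets examined one by one, 2 of them unnamed, 68 differed between the tissues (SE 0.11 to 0.26, largest adjusted p = 0.0395). The effect was more positive in roots for 30 of the 68. Over all probe sets 1226 of 22746 differed. Many of the 112 were picked for large changes in a tissue or for this difference, so their higher share follows in part from the choice. The root minus leaf differences in log2 change were 4.00 for AT5G10040, 3.40 for AT2G17850, 2.86 for AT4G33560, 2.64 for AT1G49570, 2.46 for AT5G19890, 2.25 for AT4G39675, 2.18 for AT5G66985, 2.08 for AT4G10270, 1.83 for AT4G33720 and 1.72 for AT3G29970. Differences from 1.60 to 1.05 were found for AT4G12490 (1.60), AT2G30670 (1.53), AT5G52710 (1.47), AT2G16660 (1.44), AT3G10040 (1.40), AT3G46280 (1.39), AT1G19530 (1.32), AT5G35940 (1.29), AT2G43620 (1.17), AT5G39520 (1.12) and AT1G51850 (1.05). The smaller positive ones were AT4G19430 (0.90), AT1G33055 (0.83), BCAT4 (0.80), AT4G22610 (0.78), the unnamed probe set with the greatest fall (0.76), AT3G13610 (0.71), IAA29 (0.68), LBD29 (0.62) and GI (0.50).

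On the negative side were 38 probe sets, with differences of -2.64 for AT1G05575, -2.48 for STZ, -2.31 for AT4G29780, -2.29 for AT1G73120, -2.24 for AR781 and -2.18 for ECS1. They continued with AT1G35210 (-1.93), AT5G17350 (-1.90), AT2G39650 (-1.90), XTH26 (-1.89), AT2G41730 (-1.89), AT3G01830 (-1.88), AT2G25735 (-1.83), AT1G19210 (-1.75), AT1G72920 (-1.75), AT4G37290 (-1.74), AT4G26010 (-1.72), AT1G15010 (-1.66), AT5G38910 (-1.59) and ORA47 (-1.53). Next were AT4G25790 (-1.45), WRKY53 (-1.39), AT4G27657 (-1.39), AT4G27654 (-1.35), AT1G66090 (-1.33), AT1G05310 (-1.26), APS3 (-1.18), AT5G47610 (-0.99), EXPA7 (-0.96), BHLH101 (-0.89) and AT4G29700 (-0.87). The smallest were EXPA8 (-0.81), AT3G61390 (-0.80), XTH19 (-0.79), AT1G30870 (-0.68), CML38 (-0.66), GSTU25 (-0.57) and XTH18 (-0.51).

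For 7 of the 13 lists the mean root minus leaf difference was past the threshold (camera). It was 1.29 for hypoxia response (adjusted p = 3.53e-12, and 8.74e-04 with an estimated correlation). In the same order, it was -1.51 for touch and wound (5.14e-08 and 0.00254) and -0.82 for root hair growth (1.16e-06 and 0.0117). The 5 root hair genes that fell in roots were dim in wild type leaves (4.28 to 5.29), so a fall there could hardly have been seen. Calls lost with an estimated correlation were those of expansins outside root hairs (-0.35, adjusted p = 0.00501 and then 0.166), auxin (0.31, 0.00243 and then 0.0555), sulfate (-0.34, 0.0341 and then 0.166) and alternative respiration (-0.28, 0.0430 and then 0.168).

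Of the 7 named hypoxia genes 4 rose in cys-c1 roots and 2 fell in leaves. Of the 3 named touch and wound genes all 3 fell in roots and 1 rose in leaves. Both list calls in leaves were lost with an estimated correlation (adjusted p = 0.168). A shift of whole arrays was argued against, since it cannot move the difference between the 2 lists within an array. The root minus leaf effect on that difference was 2.80 log2 (SE 0.12), which restates the list differences of 1.29 and -1.51 and is no separate test. A single array was argued against too, with a highest adjusted p of 3.73e-07 over both lists and 12 arrays left out. Scaling that depends on signal level stays open, because renewed quantile normalisation (highest adjusted p = 3.96e-08) moved the list means little, and so does harvest time or handling of the plants, because only 1 clock gene was named (GI, log2 change -0.45 in leaves and 0.05 in roots) and no harvest time is given. A different response of the organs to loss of CYS-C1 may also account for it and was not tested. It cannot be told apart from handling that differed between the tissues.

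Of the 8 named root hair genes 5 fell in cys-c1 roots, and the camera call of their list was lost with an estimated correlation (adjusted p = 0.0760). Shoot tissue in the mutant samples was argued against by the median log2 change of the green tissue markers, -0.04. In wild type roots these markers lay from 5.95 (SBPASE) to 9.88 (LHCB4.1), so green signal was present there, without a rise in cys-c1. In wild type leaves they lay from 12.51 (PRK) to 14.05 (RCA). A single array was argued against by a highest adjusted p of 3.88e-09 at the preset correlation over 6 arrays left out. Fewer or shorter hairs per root, or lower transcript levels in each hair cell, may each give this pattern. With 2 named markers of other root cells these cannot be told apart.

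In leaves 69.8% of calls were higher in cys-c1. Without wild type replicate 3 the share was 64.0%, so that this array alone was not the cause. Scaling stays open, since the leaf arrays already shared nearly one distribution and rescaling, with a lower share of 67.9%, moved little. A difference in RNA quality stays open as well, since the lowest exact permutation p of the 3′ minus 5′ differences in leaves was 0.1, the smallest that 3 against 3 allows, and a biological cause was not tested.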

How the results depend on the processing

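Array weights and all probe sets as the background were chosen only after the results were seen; the rest was planned. No named gene past the threshold and no called list changed its direction in the alternatives run for it, but the balance of root calls turned when arrays were centred on their medians, to 639 higher and 606 lower. Of 93 calls of named genes, 38 held in every alternative. The unmoderated test kept 32 of 53 in roots and 6 of 40 in leaves, and an adjusted p under 0.01 kept 48 and 32. Apart from these 2 settings 79 held throughout and 14 were lost at least once, 6 of them only when an array was left out. The count in leaves was 734 and became 1143 with an intensity trend and robust prior (711 of the 734 shared), 1668 in a single fit over 12 arrays (728 shared) and 1153 with array weights, which also gave 301 probe sets in both tissues. At an adjusted p under 0.01 the counts were 726 in roots and 243 in leaves, and an unmoderated test gave 321 and 26 (3041 and 3278 at an unadjusted p under 0.05). With an estimated correlation 2 lists were called in roots and 0 in leaves, where fry called 4 and 6. By fry, which tests a list against no change and not against other genes, the auxin list was not called in roots (adjusted p = 0.0655). The sulfate call in leaves was lost without dim probe sets (adjusted p = 0.134). With each array left out, counts ran from 751 to 1901 in roots, from 272 to 773 in leaves, from 100 to 235 in both tissues and from 855 to 1389 for the difference, and lists called in leaves from 3 to 5. Without cys-c1 replicate 3 of roots the count was 751, without wild type replicate 1 of roots 1901, without cys-c1 replicate 2 of leaves 272 and 100 in both tissues, and 3 lists were called without wild type replicate 3 of leaves. Fewer arrays lower the power of a test, and the cause of the other shifts was not tested. With the replicate number as a block the count was 1296 in roots, 441 in leaves and 1164 for the difference, and the leaf calls of WIP4, XTH18, GI, F6H1, UGT74C1 and AT3G01830 were not past the threshold (adjusted p from 0.0552 to 0.0836). Same-numbered arrays correlated in their deviations by 0.201, 0.0853 and 0.0137 in roots and by 0.0811, 0.0748 and 0.0884 in leaves. Each wild type array but root replicate 3 correlated best with its own number. Not every correlation was over the limit of 0.1, so the main fits took the arrays as unpaired. These values do not exclude pairing by number, and the leaf count depends on that choice. The planned values for CYS-C1 were not run, since no probe set is named for it. Splits of 3 against 3 are too few for a share under 0.05; the real values and the highest of the other splits were 1238 and 0 in roots, 734 and 0 in leaves, 151 and 0 and 51 and 0 for changes of at least 2-fold, and 5 and 3 (roots) and 5 and 1 (leaves) for lists. Dim probe sets limit the leaf values of root hair genes, which lay near the lower end of the signal.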

Other observations

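The gene families, the neighbouring genes and the chromosome 3 test were chosen only after the results were seen. Of 39 families of at least 6 named genes that share a symbol prefix, calmodulin-like (CML) genes, which bind calcium, stood apart in roots. CML37 (log2 change -0.98, SE 0.10), CML23 (-0.80, SE 0.07), CML38 (-0.60, SE 0.11) and CML42 (-0.47, SE 0.08) fell there, 4 of 7 members (camera, adjusted p = 0.00136; adjusted p = 0.508 with an estimated correlation). In leaves CML42 rose by 0.57 (SE 0.09). The root effect minus the leaf effect was -1.13 for CML37, -1.03 for CML23 and -1.04 for CML42, all past the threshold. Plant U-box (PUB) ubiquitin ligases, some of which act in immune signalling, had 4 of 9 members that fell in roots, PUB23 (-0.81, SE 0.09), PUB19 (-0.38, SE 0.08), PUB22 (-0.34, SE 0.07) and PUB24 (-0.28, SE 0.06), with an adjusted p = 0.0598 for the family. In leaves PUB23 (0.77, SE 0.09) and PUB25 (0.53, SE 0.12) rose (adjusted p = 0.0202; adjusted p = 0.739 with an estimated correlation), and the PUB23 effect differed between tissues by -1.58 (adjusted p = 1.01e-06).

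Tau-class glutathione transferases, which conjugate glutathione, split in roots. GSTU20 (0.79, SE 0.13), GSTU21 (0.53, SE 0.07) and GSTU27 (0.51, SE 0.09) rose and GSTU25 (-0.67, SE 0.08) and GSTU28 (-0.43, SE 0.09) fell among 11 members (family adjusted p = 0.266). The EXPA expansins were lower in roots, with 2 of 10 members called (camera, adjusted p = 0.0134; adjusted p = 0.862 with an estimated correlation), both of them root hair genes named before. The PRA group was also lower there, with PRA1.G1 and PRA1.G2 (both -0.42) called of 11 (adjusted p = 0.0139; adjusted p = 0.862 with an estimated correlation). None of 16 mitochondrion-encoded and 69 plastid-encoded genes was called in either tissue by limma, and their medians in leaves were 0.13 and 0.11 (camera, adjusted p = 0.147 for both).

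The unnamed probe sets with the greatest falls in both tissues, singled out after their values were seen, had log2 changes of -6.07 and -6.83 and of -3.26 and -2.95 (roots and then leaves). Their genes are left open. Whether either of them measures CYS-C1, for which no probe set is named here, was not tested.

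Neighbours were taken among the 13217 named genes placed on a chromosome, so unnamed loci may lie between them. In roots such neighbours changed in the same direction more often than in shuffled orders, in 33 adjacent pairs. The 10000 shuffles had a mean of 13.9 and a maximum of 30 (permutation p = 1e-04, the smallest these can give). Among the 33 pairs were GSTU21 and GSTU20, AT5G52710 and AT5G52720, and the run of AT4G27652, AT4G27654 and AT4G27657. Another was AT3G61260 and AT3G61300, close to CYS-C1 by locus number. In leaves there were 8 pairs against a mean of 4.97 (permutation p = 0.13), which leaves the question open. Shared control of neighbours, or probes that hybridise to related copies, may give the root value, and the test does not tell these apart. Of 27 named genes changed in the same direction in both tissues, 6 lay on chromosome 3, where the inserted gene lies, against 5.54 by random draws (one-sided permutation p = 0.486), so that a linked background stays open.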
